A study of Populus deltoides x Populus x canadensis with 6 samples.

How the data were processed

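RNA was measured by sequencing in 6 stem libraries of the hybrid poplar clone Nanlin 895, 3 of the wild type and 3 of a line labelled as mutant in 4 members of the pdbri1 gene family. Per the labels, plants were 45 days old and were grown in a greenhouse with 16 h of light and 8 h of dark. Each library was made from the leafless basal 2 cm of the stem of 30 plants pooled together, and 3 such pools were described as biological replicates of each genotype. P-values measure the spread between these pools. The aligner, the counting tool, the genome build, the strand setting and the rule for reads that fit several genes are not given in the sources used here.

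The series holds 1 table with 35792 rows. The deposited count columns hold raw counts per gene, as whole numbers with totals that differ between libraries, and the count unit was taken from the file headers. The deposited FPKM columns hold FPKM, a count scaled by gene length and library total, per the file headers. Dividing each count by its FPKM and the library total gave, after unit scaling, a whole number of bases (within 0.01 bp) for 100% of the 185484 values above 0, so the authors' FPKM rest on 1 fixed length per gene and on the column total of the counts. These lengths run from 84 to 17056 bp, with a median of 1708 bp, and are the only gene lengths used here. All columns of per-sample values matched 1 sample by title, and 0 were left unused.

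Gene identifiers are printed as the table gives them. The Potri identifiers named here end in v4.1, a version suffix, and how well that gene set matches the hybrid clone was not checked. Of the rows, 34488 carry a numbered chromosome in the identifier, 211 a scaffold outside the numbered chromosomes, and 1093 rows stand outside the Potri numbering. The table pairs no identifier with a gene name: its description column is empty in every row, and 0 entries of its symbol column hold a symbol other than the identifier. For 2010 of the genes tested below, that column holds no symbol. Consequently the 29 gene lists fixed before the data were examined (brassinosteroid receptors, signalling and synthesis, cambium, secondary wall, lignin, phloem, other hormones, cell type markers, stress and handling) had 0 matched members. Their tests were not run, and the transcript levels of the BRI1 genes themselves were not analysed here, since the files do not pair identifiers with names. The rule for genes to be named took the BRI1 genes, the 4 largest rises and 4 largest falls with a known function, and members of those lists, so it named none. Instead the 2 largest rises and the 2 largest falls were named by the rest of the same rule: an adjusted p under 0.05, a mean level above the median of the tested genes, and all 3 mutant libraries beyond all 3 wild type libraries. This shortened rule was set after the data were seen. The order of identifier numbers within a chromosome was taken as the order of genes, an assumption from the naming convention. No coordinates were used, and whether these chromosome numbers and this order hold in the genome of the hybrid clone was not checked.

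Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr at its default settings (a minimum count of 10 and a minimum total of 15), which left 27382 rows; of the 8410 rows left out, 2807 had no count in any library. Libraries were scaled by TMM factors, and the quasi-likelihood F test (glmQLFit with robust=TRUE, glmQLFTest) compared genotypes with no block. Log2 fold changes are mutant over wild type. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05; a subset changed at least 2-fold is given beside it. CPM values are scaled by TMM. Single values per library were compared by a two-sided exact permutation test over all assignments of 3 and 3 libraries, which cannot give a p under 0.1.

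The test was tried on 5 simulated data sets with the 27382 genes, library sizes and dispersions of these libraries and 200 changed genes in each. It recovered 38.0% of the genes changed 1.2-fold, 78.4% of those changed 1.5-fold, 90.8% of those changed 2-fold and 97.6% of those changed 4-fold, and 55 of its 817 calls (6.73%) were false. With so few changed genes the adjusted threshold was stricter than with the 17558 calls of the real comparison, so these shares do not give its recovery.

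Total counts per library ran from 17752822 to 21096052. The common biological coefficient of variation was 3.90%. Replicates were compared pair by pair over genes with at least 20 counts in the pair together. The chi-square statistic per gene was 1.84 to 1.97 between wild type libraries and 2.32 to 2.62 between mutant libraries, where sampling noise alone gives about 1. Each was therefore counted as a separate library. That each came from its own pool of plants rests on the labels and not on this comparison. A count of 0 in a group allows up to 3 counts over that group, and ratios against such a group use that floor; intervals and floors cover counting error only. Reads without molecular identifiers are not independent molecules.

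Genes counted in only 1 genotype were those with 0 counts in all 3 libraries of one genotype and at least 10 in each library of the other. Blocks of neighbouring genes that shift together were sought as highest-scoring stretches along the identifier order (log2 fold change limited to 2, minus an offset of 0.4, the only setting used), with 1000 shuffles of all genes as the comparison (Python 3.11.15, numpy 2.4.6, pandas 2.3.3); this search was added after the data were seen. Alternatives fixed before the data were examined were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma 3.58.1 with voom, no filter and a filter at 1 CPM, limma on log2(FPKM + pseudocount) with pseudocounts of 1, 0.1 and 0.01 for genes with a mean FPKM of at least 1, the replicate number as a block, each library left out in turn, and the 50 most abundant genes left out. Size classes and blocks were also recomputed under each scaling, and the main fit was repeated with the mutant libraries shifted towards falls by a common offset of 0 to 0.8 log2 in steps of 0.05; both were added after the data were seen.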

Results

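The stem transcriptome was compared between wild type hybrid poplar and a line labelled pdbri1-1;2;3;6, in which 4 members of the BRI1 family are mutated. BRI1 is the plasma membrane receptor kinase for brassinosteroids, the steroid hormones of plants. The series asks how brassinosteroids act on the vascular cambium of the woody stem, the dividing layer that produces wood and bark, and the table used here answers what differs in RNA levels between these genotypes. There were 3 pooled libraries per genotype. Wild type libraries held 17954948, 20442247 and 21096052 counts, and mutant libraries 20756647, 17752822 and 18351005 counts. The table pairs no identifier with a gene name, so the comparison is given by identifiers and by groups of genes (abundance class, identifier class, chromosome and chromosomal block). Which identifiers are the mutated receptor genes was not analysed here, so the genotype labels were not checked against them.

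The mutant stem differed widely from the wild type. Of 27382 genes tested, 17558 (64.1%) passed an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 9059 of them higher and 8499 lower in the mutant. A change of at least 2-fold was found for 5121 genes (18.7% of those tested), of which 3699 were higher and 1422 lower. A change of at least 4-fold was found for 1993 genes, 1601 higher and 392 lower, and one of at least 16-fold for 468 genes, 417 higher and 51 lower. Tested against a fold of 2 rather than against no change (edgeR's glmTreat, added after seeing the data), 2646 genes were higher and 914 lower.

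The genotypes separated far beyond the spread between replicates. Levels of 18381 genes (67.1%) did not overlap between the 3 mutant and the 3 wild type libraries, where chance gives 10%. Across genes, Spearman's rho was 0.996 to 0.997 between wild type libraries, 0.996 between mutant libraries and 0.927 to 0.931 between genotypes; genes are not independent replicates. The first principal component held 90.8% of the variance and parted the genotypes.

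**Figure D1:**
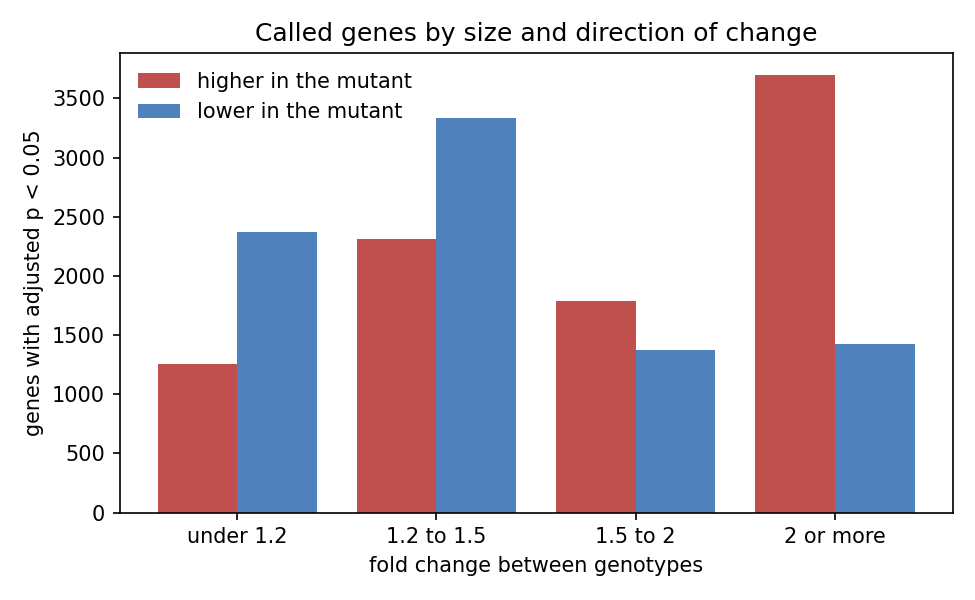
Number of genes past an adjusted p of 0.05 (y axis) in 4 classes of fold change (x axis), with red bars for genes higher and blue bars for genes lower in the mutant. Among changes under 1.2-fold, 1258 genes were higher and 2372 lower, whereas among changes of 2-fold or more 3699 were higher and 1422 lower (TMM factors; with library totals the 2 smallest classes held more genes higher than lower).

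Large changes were mostly rises, and the direction of small changes depended on the scaling. With TMM factors, under 1.2-fold, 1258 called genes were higher and 2372 lower, and between 1.2- and 1.5-fold 2313 were higher and 3331 lower. Between 1.5- and 2-fold, 1789 were higher and 1374 lower. With library totals only, the smallest class held 1999 higher and 1688 lower genes, and the class of 1.2- to 1.5-fold held 3355 higher and 1935 lower. Of all calls, 51.6% were higher with TMM factors and 66.8% when only library totals were used, a setting that moved the median log2 fold change of all genes from 0.01 to 0.13. The excess of rises among 2-fold changes was present with both, at 2.60 rises per fall with TMM and 3.58 with library totals.

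Genes of low abundance held most of the large rises. In the quartile of tested genes with the lowest mean level, 1986 genes rose and 632 fell at least 2-fold, together 38.2% of that quartile. In the quartile with the highest mean level, 370 rose and 253 fell, together 9.10% of that quartile. The ratio of rises to falls was 3.14 (95% exact interval 2.87 to 3.44) in the lowest quartile and 1.46 (1.24 to 1.72) in the highest. These intervals take genes as independent of each other. The classes also shifted as a whole, with median log2 fold changes of 0.30, 0.07, -0.03 and -0.10 from the lowest to the highest quartile (TMM factors). The scalings tried move all genes of a library alike and cannot remove such a trend with level. More genes were counted in the mutant as well. At least 1 count was found for 30484 ± 85 genes in the wild type and 31344 ± 89 in the mutant (SD, n = 3 each), and every mutant library exceeded every wild type library (two-sided exact permutation p = 0.1, the smallest this design can give).

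A few very abundant transcripts of the wild type stem fell to a small part of their level in the mutant. The 3 most abundant genes among the 2-fold falls took 5.45% ± 0.20 of all counts in the wild type and 0.144% ± 0.006 in the mutant (SD, n = 3 each), 37.8-fold less. They stand at positions 871, 872 and 874 of chromosome 13 in identifier order, and were chosen after their values were seen. Whether they are near-identical copies that share reads was not analysed here, so their separate values are uncertain. The first fell from 30762 ± 520 to 661 ± 20 CPM (SD, n = 3), by 46.5-fold (adjusted p = 4.37e-62, edgeR). The other two fell by 50.4-fold and 26.2-fold (adjusted p = 3.2e-15 and 9.32e-06, edgeR). The 10 most abundant genes of each library held 8.27% ± 0.19 of counts in the wild type and 2.85% ± 0.05 in the mutant (two-sided exact permutation p = 0.1 for both shares, the smallest possible). Among the 2-fold rises, the 3 most abundant genes took 0.111% of counts in the wild type and 0.345% in the mutant, with rises of 2.10-fold, 5.41-fold and 2.37-fold on chromosomes 6, 8 and 19.

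**Figure D2:**
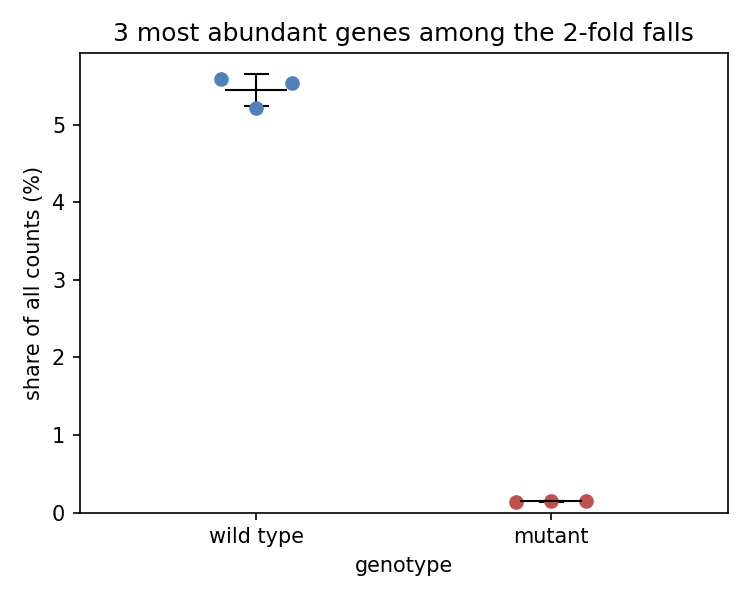
Share of all counts (y axis, percent) taken by the 3 most abundant genes among the 2-fold falls, in each library of the 2 genotypes (x axis). Points are libraries, and the bar with whiskers is the mean ± SD of 3 libraries; wild type libraries lie between 5.22% and 5.59% and mutant libraries between 0.138% and 0.149%.

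Some transcripts were present in 1 genotype and at or near 0 in the other. Potri.006G027800.v4.1, on chromosome 6 with a length of 1229 bp, had 0 counts in all wild type libraries and 1725, 902 and 1253 counts in the mutant libraries, or 64.6 ± 15.3 CPM (SD, n = 3). This is 1243-fold above the floor of 3 counts over the wild type libraries (adjusted p = 0.0097, edgeR). The lower end of the 95% exact interval of the ratio of summed counts was 1010. Potri.005G059500.v4.1, on chromosome 5 with a length of 2010 bp, had 0 counts in the wild type and 1148, 484 and 705 in the mutant, or 38.7 ± 13.4 CPM (SD, n = 3). This is 748-fold above that floor (adjusted p = 0.0205, edgeR), and the lower end of the 95% exact interval was 608. Both calls were lost when mutant replicate 3 was left out (adjusted p = 0.0807 and 0.119, edgeR), with the ratios to the floor then at 1241-fold and 771-fold. Without wild type replicate 2 the ratios to the floor were 815-fold and 491-fold, and without wild type replicate 3 they were 802-fold and 483-fold, since the same floor then stood over fewer counts. Over 20 alternatives the adjusted p ranged from 6.52e-33 to 0.0807 for the first and from 1.13e-29 to 0.119 for the other.

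The largest falls were of the same kind. Potri.004G212900.v4.1, on chromosome 4 with a length of 539 bp, had 2198, 2302 and 2175 counts in the wild type, or 118 ± 10.2 CPM (SD, n = 3), and 1, 0 and 0 counts in the mutant. The ratio of summed counts was 6948 (95% exact interval 1247 to 274459, adjusted p = 2.06e-40, edgeR). Without mutant replicate 1, which held the only mutant count, the wild type stood 1468-fold above the floor of 3 counts. The lower end of the 95% exact interval was then 1193. Potri.010G116300.v4.1, on chromosome 10 with a length of 2063 bp, fell from 489 ± 14.4 to 0.525 ± 0.544 CPM (SD, n = 3), with 25, 3 and 5 counts in the mutant libraries. Its ratio was 881 (95% exact interval 627 to 1279, counting error only), and its log2 fold change was -9.76 (adjusted p = 2.43e-07, edgeR). Most of the mutant counts came from replicate 1, and without it the ratio was 2302 (95% exact interval 1168 to 5332) and the log2 fold change -11.13.

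Genes counted in 1 genotype alone were mostly mutant genes. With at least 10 counts in each library of one genotype and 0 in all libraries of the other, 67 genes were counted only in the mutant and 4 only in the wild type. Without mutant replicate 1, 9 genes were counted only in the wild type and 72 only in the mutant. Of the 67 and 4, 65 and 4 were called by edgeR's test. The mutant-only genes had a median of 28 counts per library, and the highest had a mean of 1293. A count of 0 over the wild type libraries allows up to 3 counts, so low expression in the wild type was not excluded.

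The changed genes were found in each class of identifier. Of 26462 tested genes with a numbered chromosome, 64.8% were called, against 46.6% of 133 genes on scaffolds outside the numbered chromosomes and 42.7% of 787 genes outside the Potri numbering; these differences were not tested. Among scaffold genes changed at least 2-fold, 20 were higher and 1 was lower. Genes outside the Potri numbering took 0.482% ± 0.002 of counts in the wild type and 0.528% ± 0.002 in the mutant (SD, n = 3 each, two-sided exact permutation p = 0.1). By gene length, the longest quartile had the smallest share of genes changed at least 2-fold, 11.6%, against 22.0% in the shortest quartile.

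Changes were found on all 19 chromosomes, and the stretch of neighbouring genes with the highest score for a shared fall lay on chromosome 8. The share of called genes was 61.6% to 68.3% per chromosome, and chromosome medians of the log2 fold change lay within -0.02 and 0.05. Within chromosome 8, which had the lowest ratio of 2-fold rises to falls (1.71), a block of 109 consecutive tested genes (tested genes 1396 to 1504 of 1582) stood at 49.4% of the wild type level. In this block 92 genes were called lower and 6 higher, with a median log2 fold change of -1.02 (95% bootstrap interval over genes -1.11 to -0.92) and quartiles of -1.27 and -0.70. With library totals only, which raised the median of all genes to 0.13, the block median was -0.90 (-0.98 to -0.80), and its distance from that median was -1.03, as with TMM factors. Per library, the median log2 ratio of the block to the wild type was -1.03, -0.98 and -1.02 in the mutant libraries and between -0.01 and 0.02 in the wild type libraries. The limits of the block were set by the score, and its first edge was not sharp. Of the 20 tested genes before it, 10 were called lower and 7 higher, the nearest with a log2 fold change of 1.97, and of the 20 after it 5 were called lower and 9 higher. The 100 tested genes before it had a median of 0.10, and the 78 after it, which begin with the uncalled Potri.008G209100.v4.1 (adjusted p = 0.83, edgeR), had a median of 0.23. The score of the block was 55.7, and the highest score in 1000 shuffles of the genes was 8.24. Genes are not independent replicates, and the block was found in the data in which it was measured.

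**Figure D3:**
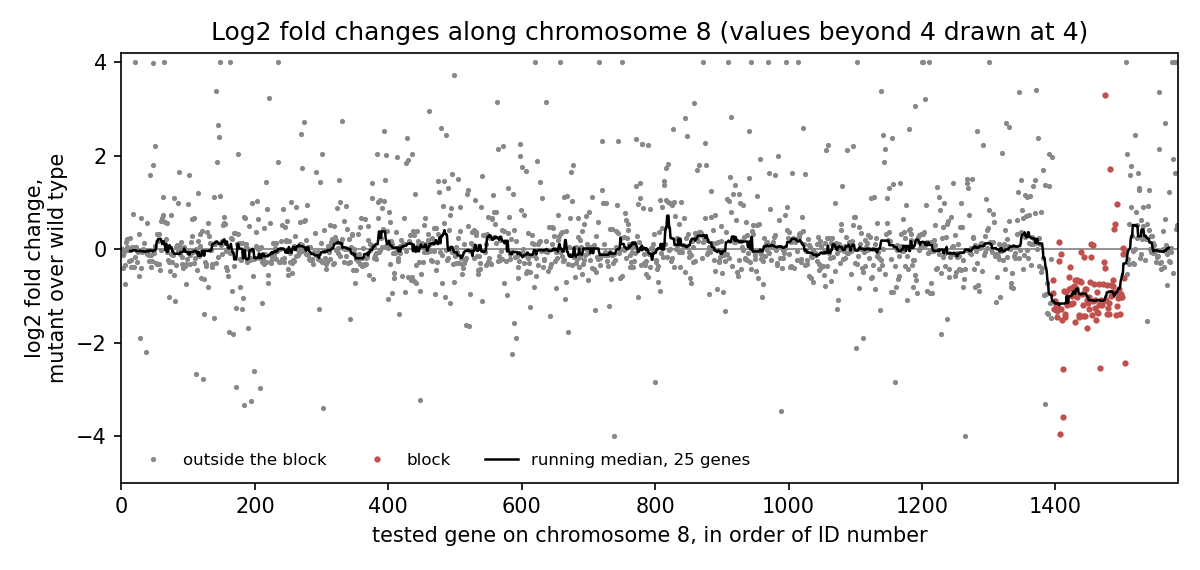
Log2 fold change of the mutant over the wild type (y axis) for each of the 1582 tested genes of chromosome 8 in order of identifier number (x axis), with the block of 109 genes in red and a running median over 25 genes as a black line; values beyond 4 are drawn at 4. The running median lies near 0 along the chromosome and near -1 in the block, whose median is -1.02.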

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

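The tests against a fold of 1.2 or 2, the scaling of size classes and blocks, the imposed shift of all genes, the runs without genes outside the Potri numbering or without the chromosome 8 block, and all settings for genes counted in 1 genotype were chosen after seeing the data. Rises outnumbered falls among 2-fold changes under each setting in which they were counted, with 2.45 to 3.58 rises per fall. The imposed shift stands apart, since it lowers the ratio by construction, to 1.05 at 0.35 log2 and to 0.92 at 0.40. The count of called genes stayed within 1.5 times the 17558 reported in each planned setting, including 15688 of 32412 genes tested by DESeq2 (48.4%, against 64.1% of 27382), and fell to 10795 when tested against a fold of 1.2, a stricter test by construction. The count of 2-fold changes fell to 2956 with limma on log2(FPKM + 1) (3941 with 0.1, 4049 with 0.01), and to 3560 when tested against a fold of 2. The pseudocount accounts for part of the first fall; the filter, scaling and test also differ there, and the rest of the cause was not tested. With FPKM, 65.3% of calls were higher, close to the value with library totals. Samples of the 2 genotypes share only a number: correlations of same-numbered deviations ran from -0.02 to -0.005, and 0 of 6 libraries correlated best with their own number. With the replicate block, 17334 genes were called and 5127 changed at least 2-fold. Leaving out each library in turn gave 16605 to 17115 called genes. Genes counted only in the mutant numbered 117 with a minimum of 5 counts, 40 with 20, and 67 with 10; those only in the wild type numbered 6, 2 and 4. Leaving out 1 library gave 72 to 98 of the former and 4 to 9 of the latter, and 9 came from leaving out mutant replicate 1. With 1 library fewer, fewer libraries have to be at 0 or at the minimum. The 4 genes named kept their direction under 20 alternatives each. This is no separate support, since they were chosen in the same data as large changes without overlap between genotypes. The 2 risers missed the threshold under 1 each (without mutant replicate 3), the 2 fallers under 0. Not run were quantile normalization, scaling to a common total and limma without trend, which were meant for a table without counts, and all alternatives for target genes and gene lists. With 17752822 to 21096052 counts per library, a gene not called is not shown to be unchanged.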

Other observations

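The search along the identifier order, the count of neighbours without the chromosome 8 block, the imposed shift of all genes and both ways of thinning the libraries were chosen after the main counts had been seen. Genes that neighbour each other changed together more often than in shuffles. Of 26443 neighbouring pairs of tested genes, 978 had both genes changed at least 2-fold in the same direction, 803 both higher and 175 both lower, against 502 to 640 in 1000 shuffles within chromosomes. Pairs changed in opposite directions numbered 303, against 317 to 447 in the shuffles. Whether neighbours are near-identical copies that share reads was not analysed here. Outside chromosome 8, 3 shorter stretches scored above every shuffle. On chromosome 10, 20 of 22 consecutive tested genes were called higher, with a median log2 fold change of 2.17. On chromosome 18, 55 of 95 genes were called higher and 14 lower (median 0.40), and on chromosome 4 all 9 genes of a stretch were called lower (median -1.37). These medians are with TMM factors.

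The block on chromosome 8 may be a segment of which the mutant line carries 1 copy fewer than the wild type. The test fixed before this result was seen asked for medians far from that of all genes. The bounds were 0.3 for a chromosome and 0.5 for 100 consecutive genes. Chromosomes stayed within 0.05, but the most extreme stretch of 100 genes, on chromosome 8, stood at -1.029. The highest stretch, on chromosome 19, stood at 0.480, just under the bound. If transcripts follow copy number, loss of 1 of 2 copies gives a log2 change of -1 and 2 copies against 3 one of -0.58; the interval of the block, -1.11 to -0.92 with TMM factors, holds the first and not the second. With library totals only, the interval of -0.98 to -0.80 holds neither. Against the median of all genes the block stood at -1.03 both with TMM factors and with library totals, which shift all genes alike, and no interval allows for the choice of the block from the same data. A regional fall in transcription remains open, no DNA was used here, and the block does not account for the other neighbouring pairs, since there were 946 same-direction pairs without its genes, above the 619 of the highest shuffle.

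Rises outnumbered falls among the 2-fold changes by 2.60 to 1, and 3 technical explanations were tested. The ratio was 2.563 or more under 4 other scalings, above the bound of 1.5 fixed beforehand against normalization as the cause, but none of these moved the median of all genes towards falls by more than 0.0045. An imposed shift of all genes towards falls lowers the ratio by construction, and shows only how far a scaling would have to go. The ratio was 1.56 at 0.20 log2 and 1.38 at 0.25, farther towards falls than any of these scalings went. That bound therefore did not decide, and normalization remains open. No scaling that depends on the level of a gene was tried. In genes above the median level the ratio was 1.80, with 1.606 as the lower end of its 95% exact interval. In each quartile of gene length the lower end was at least 1.955. These intervals take genes as independent, although neighbouring genes changed together more often than in shuffles, so they are too narrow. The first passed the bound of 1.5, also used here, by little, and in the quartile with the highest level the interval was 1.24 to 1.72. Rises still outnumbered falls in each of these groups, which argues against counts near the floor and against length as the whole cause. The ratio was smaller in abundant genes. Also open, and not tested, are the mutated genes, other changes carried by this line, and a different mix of stem cell types, for which the marker lists had no matched members.

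The 67 genes counted only in the mutant, against 4 only in the wild type, could reflect depth. After thinning every library to the smallest total, 71 of 75 such genes were in the mutant (lower end of the 95% exact interval 86.9%, with genes taken as independent). Totals scaled by TMM factors, which allow for the abundant genes of the wild type, were larger in the mutant (means of 19784902 and 19002072), and after thinning to the smallest of these 66 of 70 were in the mutant (lower end 86.01%), which argues against depth as the whole cause. If a long segment were missing from one genotype, such genes would lie in runs; 0 runs of 3 or more consecutive tested genes were found, and each of 1000 shuffles also gave 0. Gene activation, single-gene differences between the plants, and RNA from another source remain open and were not tested.

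The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The split by genotype gave 17558 called genes and 5121 changed at least 2-fold; it was the 1 split with any call by edgeR, and the highest of the other splits was 0 for both counts. In those other splits 87 to 119 genes had an unadjusted p under 0.05, and DESeq2 called at most 1 gene. Each of those splits put libraries of both genotypes in each group, so the difference between genotypes counted there as spread within groups. Their lack of calls was thus fixed in advance, and they do not show how many calls chance gives. The labels do not say whether more than 1 independent mutant line was sampled, so differences particular to a line were not separated here from effects of the mutated genes.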
